A study of Dictyostelium discoideum and Paraburkholderia agricolaris and Paraburkholderia hayleyella with 42 samples.

How the data were processed

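Gene expression was measured by RNA sequencing in 42 libraries from the social amoeba Dictyostelium discoideum, a soil amoeba that feeds on bacteria, and from Paraburkholderia symbionts, bacteria that persist inside amoeba cells. The symbiont strains were bh11 (P. hayleyella), bb859 (P. bonniea), and ba159 and ba70 (both P. agricolaris). The host strains were qs9, qs18 and qs864. Per the labels, infected hosts and intracellular symbionts were sampled 22 h after exposure, and hosts or symbionts grown alone were sampled in exponential growth.

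Per the labels' protocols, RNA from symbionts was depleted of ribosomal RNA (24 libraries) and RNA from hosts was enriched for polyadenylated transcripts (18 libraries), with a stranded library kit throughout. Uninfected host RNA was taken from whole preserved cells. Infected host RNA was the supernatant of a mild lysis that leaves nuclei in the pellet, and that pellet gave the intracellular symbiont RNA. Infection and extraction therefore changed together between infected and uninfected hosts, and between intracellular and free-living symbionts, but not between hosts that carried different symbionts. The sampling point (22 h after exposure against exponential growth) changed with infection too, so a difference in growth state cannot be told apart from infection either.

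The authors deposited 1 table of raw read counts per gene for each library, not normalized. Per the submitters' processing notes, bedtools 2.28.0, STAR 2.7.5c, Bowtie2 2.4.2, SAMtools 1.3.1, Picard 2.17.10 and HTSeq 0.11.2 were used, with no role given for any of them. The aligner of each table, the genome builds, the annotations and the strand setting of the counting are not given in the sources used here, so no coordinates are reported and overlapping or antisense genes cannot be told apart. The tables end with entries for reads assigned to no gene, which were kept out of library sizes and tests. Of all reads in a table, reads outside genes made up 0.83 to 1.49% in host libraries and 4.97 to 15.45% in symbiont libraries. Reads set aside for low alignment quality made up 5.93 to 61.99% in symbiont libraries and 0% in host libraries. Reads that aligned to several places made up 5.83 to 8.03% in host libraries, so values of multigene families (actins, polyubiquitins, the cup genes, rac1B and rac1C) are uncertain.

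Gene totals ran from 1.17 to 30.39 M counts in symbiont libraries and from 17.72 to 46.26 M in host libraries. Host identifiers were matched to the gene table of the Dictyostelium assembly dicty_2.7 for names only. Of 17138 host identifiers, 13220 matched and 4090 had a symbol, and the unmatched ones held 0.28% of the host counts. The bacterial files do not pair identifiers with names, and 0 bacterial identifiers matched, so the 15 bacterial gene lists fixed in advance could not be tested and at most 2 identifiers that rose and 2 that fell are given per strain.

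Every pair of libraries was compared by a chi-square test over genes with at least 50 counts. In 3 host pairs the statistic per degree of freedom was 1.1 to 1.15, against 21.51 to 812.37 in the other 150 host pairs. The members of each such pair differed by no more than about the sampling noise and were counted as 1 sample, with their counts summed. The comparisons had been fixed with these libraries apart, so the summing was chosen after this check. The pairs were the 2 uninfected libraries of qs18, 2 libraries of qs9, and 2 libraries of qs864. No symbiont pair came below 18.49.

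The labels of the host libraries were in conflict: in 6 of the 6 libraries of qs864 and 3 of the 6 libraries of qs9, the exposure in the title differed from the exposure in the library name. Before the data were examined, the comparisons were fixed on libraries whose labels agree on the exposure compared, and readings by title and by library name were fixed as alternatives. Infected against uninfected hosts used 7 and 2 samples of qs18 and qs9. The 2 qs864 libraries that every label gives as infected were left out, because no qs864 library is uninfected by every label. The comparisons by symbiont used 3 samples with P. agricolaris, 3 with P. hayleyella or P. bonniea and 2 uninfected, all from qs18 and qs9. The reading by library name used 15 samples: 3 uninfected and 6 for each class of symbiont, balanced over the 3 host strains. Its results are given beside the others because 2 of the 3 repeat pairs join libraries with different titles and 0 join libraries with different library names. The reading by title kept all 18 libraries apart. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

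Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter with a minimum count of 10, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. Symbiont strains were fitted separately, 3 intracellular against 3 free-living libraries. Host fits had host strain as a covariate. Differences among host strains were tested over 15 samples with no covariate. Fold changes are on the log2 scale with their standard error (SE), and CPM values are counts scaled to a common library total, computed from the deposited counts. Where a group held 0 counts, a fold is given as a bound against 3 counts over the group.

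Named genes were chosen by a rule fixed with the comparisons: among called genes with a symbol, a mean of at least 10 CPM in the higher group and no overlap between groups after removing the host strain mean, the 10 largest rises and 10 largest falls, then up to 3 members of each fixed list by p. Some genes that meet the rule are not reported here. The 13 host lists covered lysosomal and phagosomal enzymes, V-ATPase, autophagy and membrane repair, metal transport, reactive oxygen, bacterial sensing with adhesion and lectins, heat shock, early development, prestalk and prespore markers, DNA replication, cytosolic ribosomal proteins, polyketide synthases and ABC transporters. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), and with an estimated correlation and with fry as alternatives.

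Each test was checked on simulated counts with 200 changed genes. Of genes changed 4-fold, 91 to 100% were recovered in the 4 symbiont fits, and of genes changed 2-fold 70% in bh11, 76% in bb859, 19% in ba159 and 31% in ba70. The symbiont fits of the real counts called 1067 (bh11) to 4548 (ba70) genes, far more than were changed here. The adjusted p depends on the share of changed genes, so these values do not measure recovery in the real symbiont fits. In host libraries whose labels agree, recovery of 4-fold changes was 76% for infection, 59% for P. agricolaris, 49% for P. hayleyella or P. bonniea, and 75% between the classes, and that of 2-fold changes was 28, 6, 3 and 16%. In the reading by library name these values were 100, 98, 94 and 94% for 4-fold and 58, 59, 62 and 76% for 2-fold changes. Between 3 and 12 unchanged genes were called per fit.

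Per the labels, each sequencing batch held 1 free-living and 1 intracellular library of a strain, so batch pairs these libraries. The correlation of paired deviations was over 0.1 in 4 of 12 pairs (-0.28 to 0.49), among them all 3 pairs of bh11 (0.42, 0.29 and 0.49). The fit without the block had been fixed as the main one, and the blocked counts are given where they differ. No host batch held more than 1 host strain, and each strain was spread over 2 batches. Alternatives were RLE factors, DESeq2 1.42.0, no filter, removal of the 10 most abundant genes, a 2-fold minimum, batch as a block, each library left out in turn, the other label readings, repeat libraries kept apart, thinning of symbiont counts to 1.17 M, and removal of symbiont libraries with over 30% low-quality alignments.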

Results

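Transcripts of Paraburkholderia symbionts were counted in free-living culture and inside amoebas, and transcripts of Dictyostelium discoideum hosts were counted with and without symbionts. Each of the 4 symbiont strains had 3 free-living libraries and 3 intracellular libraries, 1 from each host strain. Free-living libraries held 10.74 to 30.39 M counts for bh11, 5.92 to 23.72 for bb859, 10.98 to 23.94 for ba159 and 15.41 to 19.64 for ba70. Intracellular libraries held 3.22 to 19.07 M counts for bh11, 1.6 to 4.48 for bb859, 10.36 to 15.63 for ba159 and 1.17 to 3.02 for ba70. The 18 host libraries held 17.72 to 46.26 M counts.

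The first question was how symbiont gene expression differed between life inside the host and free-living growth. In bh11 (P. hayleyella), 582 genes rose and 485 fell inside host cells, together 30.1% of 3544 genes tested. PHAYL_03039_gene rose from 14 ± 4.27 to 808 ± 193 CPM (SD, n = 3 each), a log2 fold change of 5.86 (SE 0.29, adjusted p = 8.72e-07 by edgeR's quasi-likelihood test), and PHAYL_03381_gene rose from 23.5 ± 10.9 to 1280 ± 392 CPM. PHAYL_03052_gene fell from 178 ± 26.6 to 6.1 ± 1.97 CPM, a log2 fold change of -4.82 (SE 0.27), and PHAYL_03070_gene fell from 266 ± 101 to 13 ± 3.43 CPM. A change of at least 2-fold was seen in 570 of the called genes. With batch as a block, 844 genes rose and 762 fell, 1606 in all, and without intracellular replicate 1 the count was 706.

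In bb859 (P. bonniea), 729 genes rose and 708 fell, 43.3% of 3322 genes tested, of which 828 changed at least 2-fold. PBONN_02869_gene rose from 10.5 ± 3.81 to 2560 ± 448 CPM (SD, n = 3 each; log2 fold change 7.92, SE 0.32), and PBONN_01862_gene rose by 7.80 (SE 0.22). PBONN_02727_gene, at 11700 ± 2530 CPM in free-living culture, fell to 269 ± 66.2 CPM (log2 fold change -5.45, SE 0.26). PBONN_03126_gene fell from 436 ± 146 to 14.6 ± 3.57 CPM.

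In ba159 (P. agricolaris), 2050 genes rose and 1637 fell, 51.1% of 7213 genes tested, of which 3010 changed at least 2-fold. PAGRI_01172_gene had 0 counts in the free-living libraries and 27.7 ± 8.52 CPM inside host cells (SD, n = 3), at least 481-fold higher against a floor of 3 counts over the group. PAGRI_01144_gene had 2 counts in free-living culture and 147 ± 63.4 CPM inside host cells. The neighbouring identifiers PAGRI_05579_gene and PAGRI_05580_gene both fell, from 280 ± 202 CPM (log2 fold change -6.97, SE 0.78) and from 606 ± 471 to 5.39 ± 2.79 CPM (-6.79, SE 0.77).

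In ba70, the other P. agricolaris strain, 2203 genes rose and 2345 fell, 65.4% of 6951 genes tested, of which 3641 changed at least 2-fold. PA070_02910_gene rose from 0.779 ± 0.225 to 4620 ± 1540 CPM (SD, n = 3 each; log2 fold change 12.51, SE 0.46). PA070_02968_gene had 0 counts in free-living culture and 114 ± 47.3 CPM inside host cells, at least 1760-fold higher against 3 counts over the group. PA070_06009_gene and PA070_05508_gene fell from 21.8 ± 4.47 and 41.3 ± 13.2 CPM to 1 and 3 counts over the 3 intracellular libraries. The median absolute log2 fold change of called genes was 1.04 in bh11, 1.11 in bb859, 1.54 in ba159 and 1.61 in ba70. With batch as a block, the shares of changed genes were 45.3% in bh11, 45.7% in bb859, 44.8% in ba159 and 63.4% in ba70, so the order of ba159 against bh11 and bb859 turned, and the share in ba159 was 39.7% without intracellular replicate 1. The difference between strains was not tested gene by gene. All 16 genes named for the symbionts passed the test in the same direction under every alternative run.

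**Figure D1:**
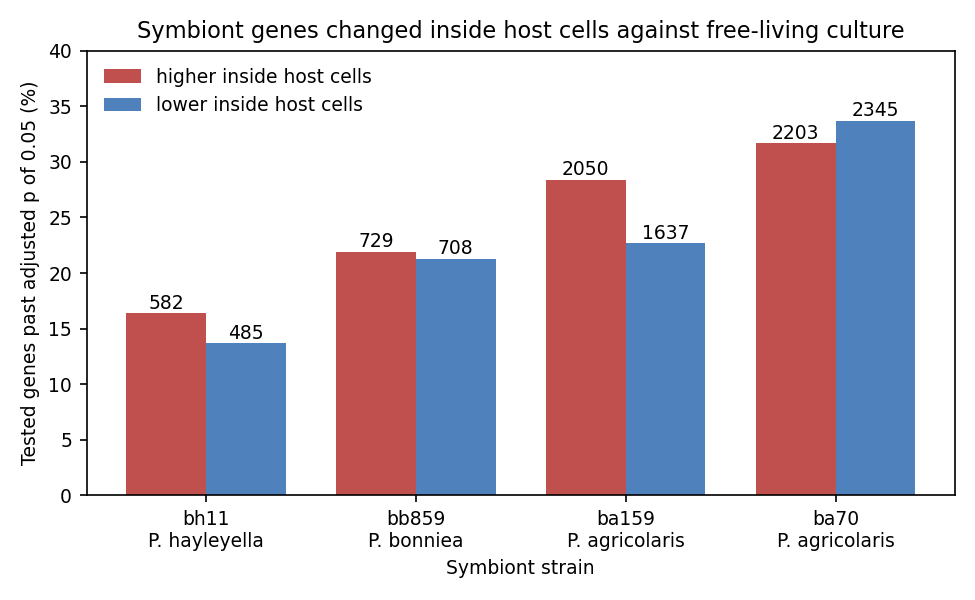
The bars give the percentage of tested genes whose counts were higher (red) or lower (blue) inside host cells than in free-living culture at an adjusted p under 0.05, per symbiont strain, with the number of genes above each bar. Without batch as a block, as drawn, the shares were 51.1% in ba159, 65.4% in ba70, 30.1% in bh11 and 43.3% in bb859; with it, ba159 had 44.8%, below bh11 and bb859.

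The host was first compared between infected and uninfected amoebas, whatever the symbiont. Transcripts of cytosolic ribosomal proteins were higher as a group in infected libraries, with 77 of 77 members above 0 and a median log2 fold change of 0.62. The list of lysosomal and phagosomal enzymes, which digest engulfed bacteria, also holds the vacuolin genes. It had a median of 0.77 with 21 of 26 members above 0. V-ATPase, the proton pump that acidifies phagosomes, had a median of 0.54 with 9 of 9 above 0. Polyketide synthases, enzymes of secondary metabolism, had a median of -0.5 with 2 of 28 above 0. Camera gave adjusted p = 1.4e-25, 6.24e-08, 9.69e-05 and 6.87e-06 for these lists, and adjusted p = 0.388 for each of them with an estimated correlation, so none of the calls held there.

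No member of any list passed the test over all genes, and 8 lysosomal genes rose when adjusted over the list alone, with none in the other 12 lists. The lysozyme gene alyA stood at 89.7 ± 52.8 CPM in 7 infected and 20.8 ± 3.88 CPM in 2 uninfected samples (SD; log2 fold change 2.09, SE 0.56, adjusted p = 0.721 by edgeR's quasi-likelihood test). The ribosomal gene rps21 stood at 1540 ± 628 against 607 ± 54.7 CPM (1.22, SE 0.31), the ABC transporter gene abcA7 at 29.7 ± 17.8 against 5.52 ± 1.97 CPM (2.4, SE 0.63) and the V-ATPase gene vatA at 1540 ± 369 against 978 ± 15.9 CPM (0.64, SE 0.27). Autophagy and membrane repair was the fifth list called by camera, with a median of 0.20 (adjusted p = 0.034, and 0.388 with an estimated correlation). Medians of the other lists were -0.12 for ABC transporters, 0.19 for sensing, adhesion and lectins, 0.13 for DNA replication, 0.10 for heat shock, -0.04 for metal transport, 0.03 for prestalk and prespore markers, 0.11 for reactive oxygen and 0.07 for early development, none called.

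Across all 9816 genes, 1 gene fell and 0 rose by edgeR's quasi-likelihood test, with 578 genes at an unadjusted p under 0.05 and 61 called by DESeq2. The gene that fell, DDB_G3957972, has no symbol, lies outside the naming rule and was named after its values were seen: 0.0388 ± 0.0472 CPM in infected and 6.37 ± 2.27 CPM in uninfected samples. With exposure read from library names, 1 other gene was called, DDB_G0278391, which rose from 0.189 ± 0.171 CPM in 3 uninfected to 8.44 ± 7.62 CPM in 12 infected samples, with 1021 genes at an unadjusted p under 0.05 and 91 called by DESeq2. In that reading the median was 0.48 for ribosomal proteins, 0.64 for lysosomal enzymes (14 genes rose when adjusted over the list alone), 0.48 for V-ATPase and -0.31 for polyketide synthases. The extraction also differed between infected and uninfected hosts. So did the share of reads outside genes in qs18 and qs9 (0.83 to 1.13% against 1.32 to 1.49% where labels agree). In qs864 this share was 0.95 and 0.94% in the libraries uninfected by library name, within the 0.85 to 0.97% of that strain. The count of 1 with labels that agree became 0 without the qs18 with ba159, qs18 with ba70, qs9 disputed infected or qs9 with bb859 sample, and 6 without qs18 with bh11. By library name, it became 0 without the uninfected sample of qs18 or qs9, qs18 with ba70, qs18 with bb859, qs9 with bh11, qs9 with ba159 or qs9 with bb859, 5 without qs18 with bh11, 2 without qs18 with ba159 and 6 without qs864 with bh11. Without the uninfected sample of qs864 the rise was not called, and 1 gene fell.

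The next comparison asked what hosts exposed to P. agricolaris expressed relative to uninfected hosts. In libraries whose labels agree, cupI fell. It belongs to the cup family, named for its rise with calcium, and stood at 67.2 ± 35.3 CPM in 3 exposed and 315 ± 175 CPM in 2 uninfected samples (SD; log2 fold change -2.02, SE 0.17, adjusted p = 0.0429 by edgeR's quasi-likelihood test). It was the only gene called of 9631, with 621 at an unadjusted p under 0.05 and 162 called by DESeq2. Lysosomal genes had the largest differences among the lists: vacC stood at 63.2 ± 67.6 against 0.0939 ± 0.0169 CPM (9.10, SE 1.70, adjusted p = 0.219 by edgeR), cprC at 24.9 ± 27.9 against 0.129 ± 0.0428 CPM (7.25, SE 1.16, adjusted p = 0.163) and alyA at 121 ± 68.1 against 20.5 ± 3.86 CPM (2.56, SE 0.47, adjusted p = 0.215). None of the 26 lysosomal genes passed over all genes, and 9 rose when adjusted over the list alone.

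With exposure read from library names, 65 genes rose and 31 fell with P. agricolaris (6 exposed and 3 uninfected samples). Among genes with a symbol, the largest rises were of lysosomal genes, and some genes without a symbol rose more. The vacuolin gene vacC, whose family sits on late endosomes, rose by 9.22 on the log2 scale (SE 1.34, adjusted p = 0.00816 by edgeR's quasi-likelihood test), from 0.125 ± 0.072 to 69.8 ± 58.3 CPM (SD). The cysteine protease genes cprC (8.63, SE 1.16), cprE (3.31, SE 0.60) and cprF (1.81, SE 0.35) rose too, cprF from 676 ± 80.6 to 2590 ± 1400 CPM. So did the lysozyme genes alyB (7.35, SE 1.27) and alyC (5.04, SE 0.99). The cathepsin B gene ctsB, which is not in the fixed lysosomal list, rose too (1.40, SE 0.30), from 236 ± 18.4 to 663 ± 305 CPM. The rule admitted the largest rises and falls only where all 6 exposed samples lay above, or below, all 3 uninfected ones once the host strain mean was removed. That separation was fixed by the choice and adds no evidence, and genes taken from the lists by p need not meet it.

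Outside the lysosomal list, the rises included osbK, of the oxysterol-binding family (3.40, SE 0.73), the actin gene act4 (1.03, SE 0.22), slob2 (0.95, SE 0.21) and the ABC transporter genes abcA7 (2.60, SE 0.46) and abcA8 (3.65, SE 0.69). The falls included genes of small GTPases, which regulate the actin cytoskeleton and signalling: rac1B fell from 25.9 ± 15.2 to 3.58 ± 2.23 CPM (-2.80, SE 0.39), rasY from 18.7 ± 5.67 to 6.55 ± 4.1 CPM (-1.65, SE 0.32) and rac1C from 11.2 ± 14 to 3.25 ± 2.71 CPM (-1.41, SE 0.27). The ABC transporter gene abcG2 fell from 180 ± 34.7 to 61.0 ± 32.5 CPM (-1.75, SE 0.26), the polyubiquitin gene ubqH by 1.14 on the log2 scale (SE 0.23), cpras1 by 0.92 (SE 0.17) and egeA by 0.73 (SE 0.16). Among genes without a symbol, DDB_G0280727 rose from 0.0478 ± 0.0055 to 63.4 ± 97.2 CPM and DDB_G0281635 from 2 counts over the uninfected samples to 35.6 ± 67.7 CPM, and DDB_G0282121 and DDB_G0275547 fell by 1.79 and 1.74.

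By list, 6 of 26 lysosomal genes rose and 0 fell over all genes, with 16 up and 1 down when adjusted over the list alone (median 0.80; camera adjusted p = 1.31e-10, and adjusted p = 0.378 with an estimated correlation). Fry called this list in a single direction (adjusted p = 0.0119). Of 9 V-ATPase genes 0 passed over all genes and 7 rose when adjusted over the list alone (median 0.51; camera adjusted p = 3.28e-05, and adjusted p = 0.437 with an estimated correlation), vatA standing at 1620 ± 359 against 1010 ± 35.0 CPM. Of 63 ABC transporter genes 2 rose and 1 fell, with 3 up and 2 down when adjusted over the list alone. The cyclin gene cycA stood at 25.0 ± 5.99 against 39.3 ± 6.64 CPM (-0.66, SE 0.15, adjusted p = 0.0507 by edgeR), and cupI was not called in this reading (-1.27, adjusted p = 0.156 by edgeR).

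All 94 of the genes called by library name that were tested in the libraries whose labels agree had the same direction there, 92 of them at an unadjusted p under 0.05, although these libraries are part of both sets. Read by title, 0 genes were called, and the single call by agreed labels became 0 with RLE factors, 36 with no filter, 53 with repeat libraries kept apart, 19 without qs18 with bb859, 2 without qs18 with bh11, and 0 with batch as a block or without the uninfected sample of qs18 or qs9, qs18 with ba159, qs18 with ba70, qs9 with ba70 or qs9 with bb859. Where the call on cupI was lost with agreed labels its fold stayed between -1.95 and -2.07, and by title it was -0.85. By library name, the count of 96 became 0 without the uninfected sample of qs18 or of qs9, 13 without that of qs864, 46 without qs18 with ba159, 50 without qs9 with bh11, 54 without qs9 with bb859, 61 without qs9 with ba159, 191 without qs864 with ba159 and 421 without qs18 with bb859.

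**Figure D2:**
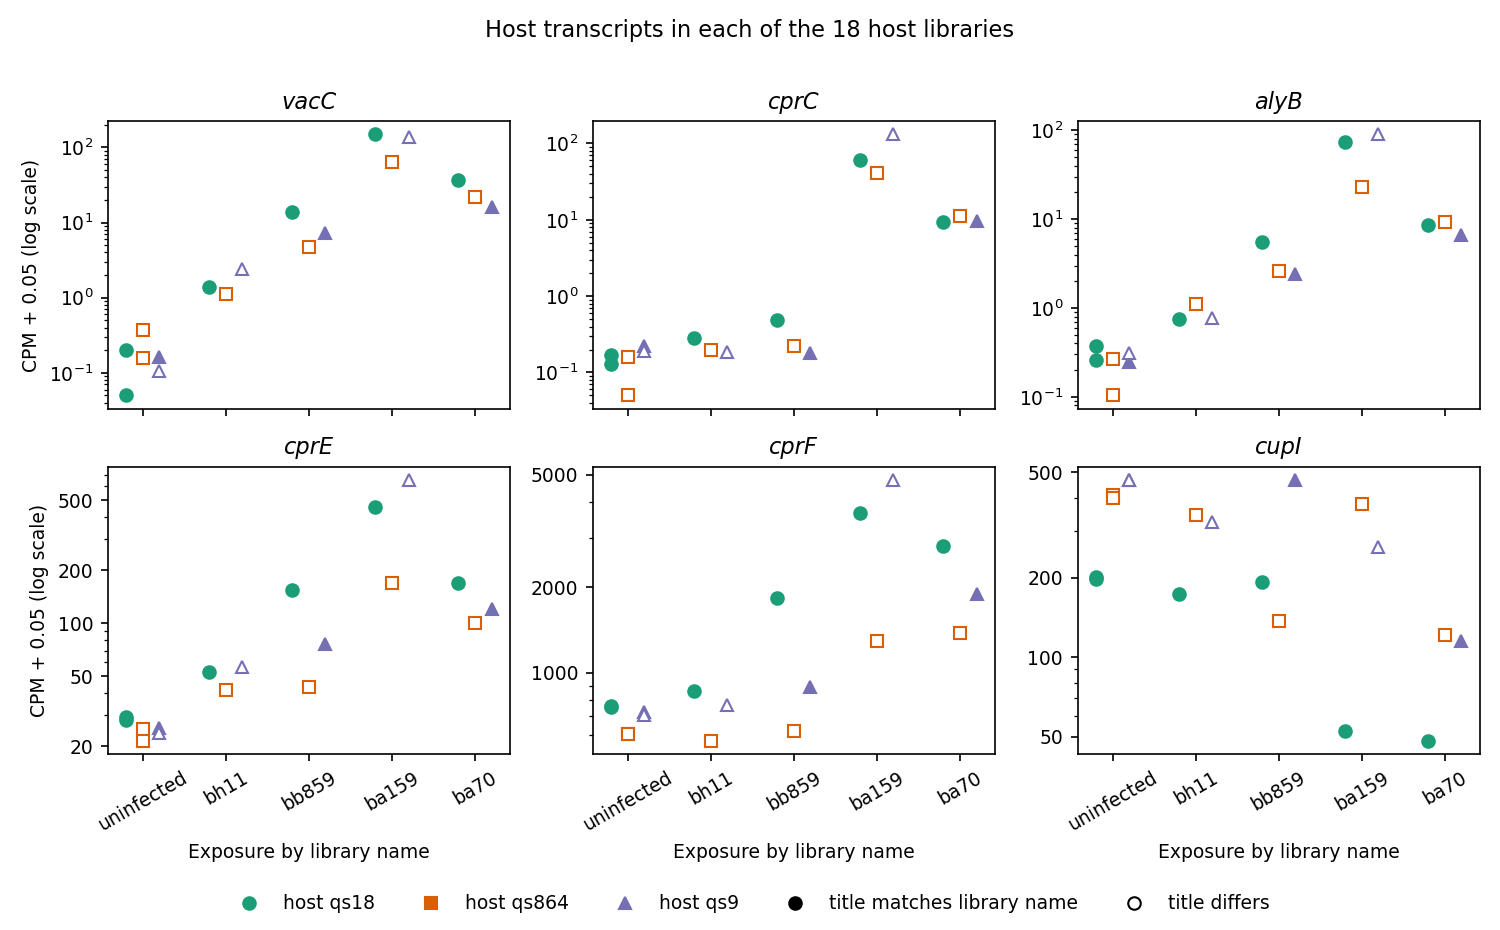
Each point is 1 host library, placed by the exposure in its library name (x axis) and its CPM plus 0.05 (y axis, log scale) for 6 genes, with shape and colour by host strain and open symbols where the title gives another exposure. All 6 libraries named for ba159 or ba70 had 9.38 to 131 CPM of cprC, and the other 12 had 0 to 0.432 CPM, while cupI did not separate in this way.

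Hosts exposed to P. hayleyella or P. bonniea, whose tables list fewer genes than those of P. agricolaris, were next compared with uninfected hosts. In libraries whose labels agree, 0 of 9631 genes were called by edgeR's quasi-likelihood test, with 286 at an unadjusted p under 0.05 and 16 called by DESeq2. Ribosomal protein genes had a median log2 fold change of 0.73 with 77 of 77 above 0 (camera adjusted p = 1.9e-24, and adjusted p = 0.564 with an estimated correlation), and rps21 stood at 1700 ± 862 CPM in 3 exposed against 599 ± 53.2 CPM in 2 uninfected samples (SD; 1.34, SE 0.40). The samples differed in this shift: the list mean lay 0.02 above the uninfected sample of its strain in qs18 with bh11, 1.24 in qs18 with bb859 and 0.70 in qs9 with bb859, and the median was 0.37 without qs18 with bb859. The 26 lysosomal genes had a median of 0.61 (camera adjusted p = 6.84e-05, and adjusted p = 0.564 with an estimated correlation), none passed when adjusted over the list alone, and read by title their median was -0.17. Within that list vacC stood at 7.06 ± 5.86 against 0.0939 ± 0.0169 CPM (6.22, SE 1.58) and cprB at 1.47 ± 1.07 against 6.26 ± 2.64 CPM (-2.03, SE 0.49), both with an adjusted p of 0.85 by edgeR. Prestalk and prespore markers had a median of -0.78 with 4 of 17 above 0, not called by camera (adjusted p = 0.205). By library name their median was -0.01 with 9 of 18 above 0.

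By library name, 2 genes rose in hosts with P. hayleyella or P. bonniea (6 samples against 3), with 776 at an unadjusted p under 0.05 and 41 called by DESeq2. Neither has a symbol and both were named after their values were seen: DDB_G0278391 rose from 0.189 ± 0.171 to 9.77 ± 8.66 CPM (SD) and DDB_G0291706 from 0.179 ± 0.134 to 2.82 ± 1.18 CPM. Of the lysosomal genes 2 rose when adjusted over the list alone (median 0.50; camera adjusted p = 2.24e-05, and adjusted p = 0.58 with an estimated correlation). The ribosomal protein median was 0.45 (0.2 without qs18 with bb859) and the V-ATPase median 0.42. The count of 2 became 4 without qs18 with bh11, 6 with no filter (4 rose), 56 with repeat libraries kept apart (31 rose), 1 without qs18 with bb859, qs9 with ba159 or qs864 with ba159, ba70 or bb859, and 0 without the uninfected sample of qs18 or qs9, qs18 with ba70, qs864 with bh11, qs9 with bh11 or qs9 with bb859. Without the uninfected sample of qs864 neither rise was called, and 1 gene fell.

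**Figure D3:**
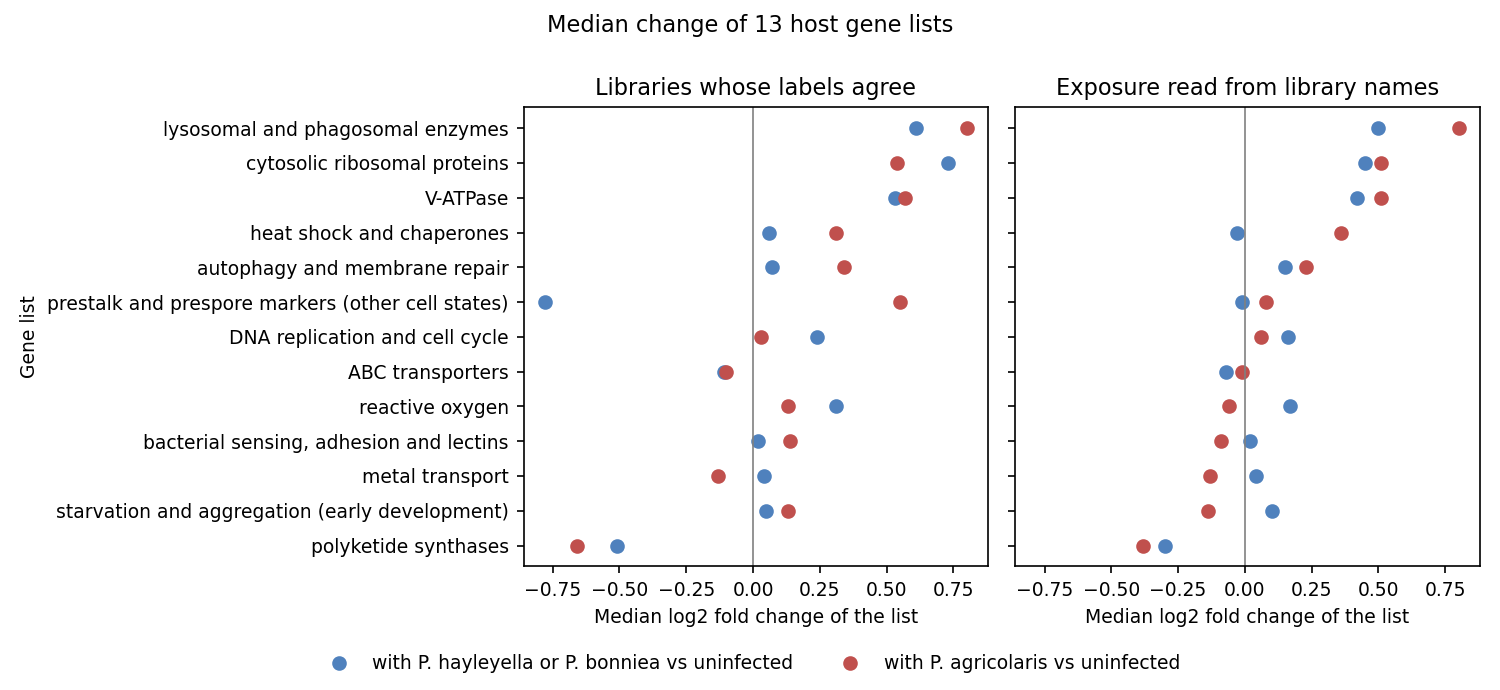
Points give the median log2 fold change (x axis) of each of 13 gene lists (y axis) against uninfected hosts, for hosts with P. hayleyella or P. bonniea (blue) and hosts with P. agricolaris (red), in the libraries whose labels agree (left) and with exposure read from library names (right). Lysosomal enzymes, ribosomal proteins and V-ATPase lie above 0 and polyketide synthases below 0 for both classes in both panels.

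The classes of symbiont were then compared with each other, which involves no difference in extraction. In libraries whose labels agree, cupI was higher with P. hayleyella or P. bonniea than with P. agricolaris, at 264 ± 158 against 67.2 ± 35.3 CPM (SD, n = 3 each; 1.94, SE 0.16, adjusted p = 0.0324 by edgeR's quasi-likelihood test). It was the only call, with 485 genes at an unadjusted p under 0.05 and 106 called by DESeq2. The protease gene cprC stood at 0.252 ± 0.145 against 24.9 ± 27.9 CPM (-6.54, SE 0.91, adjusted p = 0.134), the adhesion gene cad2 at 5.76 ± 4.68 against 31.6 ± 6.63 CPM (-2.46, SE 0.54, adjusted p = 0.382) and the heat shock gene hspI at 9.46 ± 10.4 against 38.4 ± 20.5 CPM (-2.37, SE 0.47, adjusted p = 0.382). Of the 26 lysosomal genes 2 were lower when adjusted over the list alone (median -0.46; camera adjusted p = 1.26e-05, and adjusted p = 0.702 with an estimated correlation). Prestalk and prespore markers, genes of cells in development, had a larger median difference of -1.15 with 2 of 17 above 0, and camera did not call them (adjusted p = 0.103, and 0.702 with an estimated correlation); by library name their median was -0.02 with 8 of 18 above 0. The oxidase subunit gene ncfA (0.94, SE 0.22) and the cyclin gene cycA (0.82, SE 0.17) were each higher when adjusted over their list alone.

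By library name, 32 genes were higher and 72 lower with P. hayleyella or P. bonniea than with P. agricolaris (6 samples each). The lower genes included 5 of 26 lysosomal genes, with 10 lower and 2 higher when adjusted over the list alone: cprC stood at 0.205 ± 0.117 against 43.0 ± 47.1 CPM (SD; -7.63, SE 0.82, adjusted p = 0.00176 by edgeR's quasi-likelihood test), alyB at 2.12 ± 1.84 against 34.5 ± 36.5 CPM (-3.95, SE 0.76), vacC at 5.02 ± 4.83 against 69.8 ± 58.3 CPM (-3.84, SE 0.70), cprF at 907 ± 470 against 2590 ± 1400 CPM (-1.49, SE 0.27), and cprE differed by -1.95 (SE 0.42). Camera called the list (median -0.39, adjusted p = 1.74e-05, and adjusted p = 0.547 with an estimated correlation). It also called heat shock (median -0.26, adjusted p = 0.00312), DNA replication (0.17, 0.00312), ribosomal proteins (-0.08, 0.0192) and early development (0.24, 0.0366), none of them with an estimated correlation. The ribosomal median had the other sign where labels agree (0.19, with 75 of 77 above 0, against 3 of 77 by library name). Also lower were osbK (-3.10, SE 0.54), hspI (-2.24, SE 0.36), the chaperone cofactor gene grpE (-0.74, SE 0.15), the sideroflexin gene sfxn (-0.69, SE 0.13) and tmem14B (-0.62, SE 0.11). The unnamed DDB_G0280201 stood at 0.943 ± 0.32 against 285 ± 477 CPM.

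Genes that were higher with P. hayleyella or P. bonniea included the ATPase pump genes patB (967 ± 363 against 461 ± 172 CPM; 1.11, SE 0.21) and patA (482 ± 230 against 225 ± 41.2 CPM; 1.03, SE 0.17). The ABC transporter genes abcG2 (1.28, SE 0.22) and abcG22 (0.67, SE 0.10) were the 2 of 63 in their list, with 4 higher and 4 lower when adjusted over the list alone. The cyclin gene cycA (0.70, SE 0.12) was the only one of 26 DNA replication genes, the adhesion gene sibC (0.51, SE 0.11) the only one of 17 sensing and adhesion genes, and hspI the only one of 22 heat shock genes that was lower; each of these counts was also 1 when adjusted over the list alone. Smaller differences were called for 3B-1 (0.79, SE 0.17), slc44a2 (0.49, SE 0.10) and the phosphodiesterase gene pdeE (0.48, SE 0.10), and for the unnamed DDB_G0288055 (1.82, SE 0.30) and DDB_G0287985 (1.78, SE 0.25).

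All 104 genes called by library name had the same direction in the libraries whose labels agree, which are part of both sets, 92 of them at an unadjusted p under 0.05; by title 0 were called. The call on cupI was lost with RLE factors (1.97, adjusted p = 0.0508 by edgeR's quasi-likelihood test) and without qs18 with ba159 (2.00, adjusted p = 0.128), where the difference stayed as large, and by library name, where it was 0.95 (adjusted p = 0.258). Over its alternatives the adjusted p ran from 6.38e-28 with DESeq2 to 1 by title with edgeR. The count became 12 with no filter, 13 with batch as a block, 6 without qs18 with bb859, and 0 without the uninfected sample of qs18 or qs9, qs18 with ba70, qs9 with ba70 or qs9 with bb859. By library name, the count of 104 became 29 without qs9 with bh11, 41 without qs18 with ba159, 42 without qs9 with ba159, 55 without qs18 with bh11, 63 without qs864 with bh11 and 169 without qs18 with bb859.

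Whether the class difference or the infection effect varied between host strains was tested with interaction terms. By edgeR's quasi-likelihood test, 0 of 9431 genes were called for the class by strain term (library names; 98 at an unadjusted p under 0.05), and 0 of 9354 for the infection by strain term (labels that agree; 36 at an unadjusted p under 0.05). No other tool was run on these terms. The fits had 6 and 5 residual degrees of freedom, and the infection term rested on a single uninfected sample per strain. Recovery of known changes was not simulated for them. The absence of calls therefore does not show that the host strains responded alike.

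Host strains were compared over 15 samples, 5 per strain, whatever their exposure. In qs18, several genes were higher than in the other strains: chdh, for choline dehydrogenase, stood at 11.6 ± 3.97 CPM against 3.68 ± 0.901 in qs864 and 4.3 ± 0.594 in qs9 (SD, n = 5 each), nola1 at 215 ± 52.3 against 105 ± 27.5 and 118 ± 32.0, and smt1, for sterol methyltransferase, at 2070 ± 1000 against 1070 ± 176 and 1040 ± 213. Lower in qs18 were the polyketide synthase gene stlB (1.27 ± 0.355 against 9.13 ± 1.39 in qs864 and 10.4 ± 1.35 in qs9), the GATA-family transcription factor genes gtaQ (4.87 ± 2.12 against 26.0 ± 2.29 and 19.6 ± 1.87) and gtaW (5.25 ± 1.75 against 22.4 ± 2.78 and 18.9 ± 2.08), aslD-1, and the polyubiquitin gene ubqH.

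In qs864, GP138D was higher at 83.6 ± 9.94 CPM (SD, n = 5) against 22.2 ± 6.54 in qs18 and 26.1 ± 4.69 in qs9, as were the kinase genes samkB (283 ± 55.8 against 78.5 ± 16.8 and 97.0 ± 13.2) and dhkK (13.8 ± 1.99 against 5.34 ± 0.353 and 7.4 ± 0.832). The GTPase gene rac1C stood at 0.0974 ± 0.0478 CPM in qs864 against 4.44 ± 1.22 and 11.6 ± 8.78. In qs9, the adhesion modulator gene ampA was higher (14 ± 1.8 against 6.19 ± 0.881 in qs18 and 5.35 ± 2.42 in qs864), as was ndrJ (59.2 ± 12.1 against 25.1 ± 9.32 and 30.2 ± 8.0), and abkD was lower (16.3 ± 0.979 against 25.8 ± 4.98 and 27.3 ± 4.29). All of these genes passed edgeR's quasi-likelihood F-test over the 3 strains, with adjusted p from 1.62e-07 (stlB) to 0.0191 (smt1), and the test of the named strain against each of the others.

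In all, 1639 of 9530 genes (17.2%) differed among the strains: 1391 between qs9 and qs18, 1227 between qs864 and qs18 and 382 between qs9 and qs864. Of the fixed lists, sensing, adhesion and lectins had the highest share, 7 of 17 genes (41.2%), or 12 when adjusted over the list alone. Ribosomal proteins had 17 of 77 (42 when adjusted over the list alone), heat shock 5 of 22 (6), ABC transporters 11 of 61 (11) and lysosomal enzymes 1 of 26 (0), while autophagy, metal transport, reactive oxygen and V-ATPase had 0 both ways. Each host strain was sequenced in its own batches, so strain and batch cannot be told apart. The count became 2936 with the symbiont by library name as a covariate, 747 at 2-fold, 2641 with DESeq2, 2916 with repeat libraries kept apart and 989 without qs18 with ba70. Other alternatives changed more than 1 choice. With the symbiont by title as a covariate and all 18 libraries apart it was 2572. In samples of undisputed infection status, with infection as a covariate, it was 543.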

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

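The test of repeat pairs against titles and the test of gene length alone were chosen only after the results were seen, as were the settings with symbiont counts thinned and with low-quality libraries removed.

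Of 45 groups tested for a sample far from the others, 2 held one, and chance gives about 1 in 20. The qs864 library with disputed labels, replicate 1 (P. hayleyella by library name, uninfected by title), had a mean log2 CPM of 1.91 over prestalk and prespore markers, genes of cells in development. The qs9 uninfected sample had 1.49% of reads outside genes. In bb859, reads set aside for low alignment quality made up 30.93% in intracellular replicate 1 and 11.74% in replicate 2, above the highest free-living value of 11.68%. Other strains had higher shares: 61.99% in ba70 free-living replicate 2, 59.88% in ba70 intracellular replicate 1 and 42.85% in ba159 free-living replicate 2. No explanation of these values was tested.

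The labels of 9 host libraries disagreed between title and library name. Of the 3 pairs of libraries that matched within sampling noise, 2 joined different titles and 0 joined different library names, which argues against wrong library names with right titles. A score of 16 genes higher and 10 lower between the symbiont classes in undisputed libraries differed by 4.69 (SD 1.56) between disputed libraries of a strain read by library name, positive in 5 of 5 pairs, and by 0.44 (SD 4.09) read by title, positive in 4 of 5. In both readings all pairs but 1 reuse the same qs864 libraries, so they are not independent. This goes with wrong titles and right library names, as a hypothesis, since no source states which label is right. The score pairs hold only libraries read as infected, so these pairs do not test which disputed libraries were uninfected. Undisputed uninfected libraries scored 6.99 to 7.47 and undisputed ones with P. agricolaris -0.78 to 1.57. Disputed libraries named uninfected scored 7.44 to 7.92. Of those titled uninfected, the qs9 library named for ba159 scored -1.41, and the qs864 libraries named for bh11 and bb859 scored 6.05 and 5.56.

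Ribosomal protein transcripts were higher in infected than uninfected libraries (median log2 fold change 0.62), and 0 of 7 infected libraries lay below the uninfected library of their own strain, the lowest, qs18 with bh11, only 0.02 above it. By library name 1 of 12 did, qs864 with bh11 at -0.17, a single library that its title calls uninfected and that by itself excludes nothing. Extraction from a cytoplasmic lysate and infection cannot be told apart, because the design changed them together. Against the 10 nearest other genes in length and level, the median difference was 0.17, as predicted for a bias by length and level together. Such genes thus shared most of the shift, although 63 of 77 ribosomal genes stayed above them. Against the 10 nearest in length alone the median difference was 0.68 (SD 0.25), which argues against length by itself. In other genes, length and fold change had a Spearman rho of 0.03. The drop to 0.17 therefore came with matching on level, and a bias by level was not tested apart from a response of such genes. A response of the host to infection stays open and was not tested apart from extraction or from the sampling point.

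A larger share of genes changed in the P. agricolaris strains than in P. hayleyella and P. bonniea, by 7.9 percentage points between the nearest strains. The gap was 7.2 points after every library was thinned to the same depth, and 7.5 without libraries with many low-quality alignments, which argues against either as the whole cause of the gap in that fit. Without those low-quality libraries the shares themselves were 54.1% in ba70, 42.4% in ba159, 34.9% in bb859 and 30.1% in bh11, which had no such library. With batch as a block the gap was -0.9 points, with ba159 below bh11 and bb859, so the gap between the species depends on the fit. Extraction and a difference between the species stay open.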

How the results depend on the processing

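Thinning, the removal of low-quality libraries, the alternatives of the library-name reading and the fits per symbiont were chosen after seeing the data. So was the summing of repeat libraries, since the comparisons had been fixed with repeats apart. All 16 genes named in symbionts kept their call under every alternative run. Of the genes named for symbionts and for host exposure, none reversed a call under the alternatives run. In the P. agricolaris comparison by library name, 930 of 1100 values for named genes kept their side of the threshold, 131 lost a call and 39 gained one. Between the classes these were 972, 78 and 10 of 1060. The named genes include list members with no call in the main fit, whose values count as kept where they stayed uncalled. Losses can fall only on the called genes, so the share of calls lost was higher than these totals show. The reading by title was not among these alternatives. Where a count moved, the cause was not tested, except that a 2-fold minimum, fewer genes or fewer samples are part of the alternative itself. Batch as a replicate block gave 1606 changed genes in bh11, 0 for infection, 0 for P. agricolaris against uninfected and 13 between the classes in libraries whose labels agree, and moved no other count by over 1.5 times. A 2-fold minimum gave 570 in bh11, 828 in bb859, 67 between the classes by library name and 747 between host strains. Thinning gave 2420 in ba159. With labels that agree, infection gave 61 with DESeq2 and 0 by title. P. agricolaris against uninfected gave 0 with RLE factors, 162 with DESeq2, 36 with no filter, 0 by title, 96 by library name and 53 with repeat libraries kept apart. P. hayleyella or P. bonniea against uninfected gave 16 with DESeq2 and 2 by library name. The classes gave 0 with RLE factors, 106 with DESeq2, 12 with no filter, 0 by title, 104 by library name and 8 with repeat libraries kept apart. By library name, DESeq2 gave 91 for infection, 516 for P. agricolaris, 41 for P. hayleyella or P. bonniea and 374 between the classes. No filter gave 4, 191 and 6 in the first 3 of these, and repeat libraries kept apart gave 461, 1107, 56 and 255. Host strains gave 2641 with DESeq2, 2936 with the symbiont by library name and 2916 with repeat libraries kept apart. They gave 2572 with the symbiont by title and repeats apart, and 543 in undisputed samples with infection as a covariate. Of 52 list tests, 19 were called by camera with labels that agree and 21 by library name, 0 and 0 with an estimated correlation, and 0 and 1 by fry. Leaving out 1 library gave 706 to 1154 in bh11, 1008 to 1440 in bb859, 2913 to 3998 in ba159, 3954 to 4505 in ba70 and 989 to 1996 between host strains. With labels that agree it gave 0 to 6 for infection, 0 to 19 for P. agricolaris, 0 to 0 for P. hayleyella or P. bonniea and 0 to 6 between the classes; by library name it gave 0 to 6, 0 to 421, 0 to 4 and 29 to 169. Where 1 sample of a group was left, it was assumed to vary like the other groups. The response of ba70 against that of ba159 and the correlation across symbiont species were not run, because their identifiers share no names.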

Other observations

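The fits per symbiont and the splits that keep the samples per host strain were chosen only after the results were seen.

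With exposure read from library names, each symbiont was compared with uninfected hosts (3 samples each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 26 lysosomal genes, 13 rose over all genes with ba159, 7 with ba70, 4 with bb859 and 1 with bh11. Prestalk and prespore markers, of cells in development, had medians of -1.52 with ba159, 0.45 with ba70, -0.36 with bb859 and 0.2 with bh11, and 2.01 for ba70 against ba159, where the lysosomal median was -0.5, and none of the 18 passed the test. The vacuolin gene vacC rose by 9.94 on the log2 scale with ba159 (SE 0.56, adjusted p = 2.68e-06 by edgeR), 7.74 with ba70, 6.14 with bb859 and 3.79 with bh11, and the protease gene cprC rose by 9.38 with ba159 and 6.55 with ba70 and stood at 1.22 (adjusted p = 0.221) with bb859 and 0.65 (adjusted p = 0.999) with bh11. In all, 347 genes rose and 69 fell with ba159, 58 and 71 with ba70, 33 and 20 with bb859, and 5 and 1 with bh11. Between the P. agricolaris strains, 40 genes were lower with ba70 than with ba159, and 0 were higher, with 1161 at an unadjusted p under 0.05 in edgeR and no other tool run.

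Among single genes, acly (4.40, SE 0.68), 29C (3.57, SE 0.57) and the vacuolin gene vacB (3.34, SE 0.25) rose with ba159 and CYP519E1 fell by 0.86. With ba70, the cup family gene cupG (-1.71, SE 0.33), the polyubiquitin gene ubqJ (-1.35, SE 0.22) and pcmA (-1.28, SE 0.26) fell. With bb859, cfaC (1.47, SE 0.27) and amyA (1.12, SE 0.21) rose and rac1B fell by 2.60, and with bh11, comF-1 rose (0.93, SE 0.11). Between bb859 and bh11, edgeR called 0 genes, with 2397 at an unadjusted p under 0.05, and no other tool was run. Without the qs18 library with bb859, the counts were 821 for ba159, 643 for ba70 and 10 for bh11. For bb859, 10 genes rose and 0 fell, so the fall of rac1B was no longer called. Between the P. agricolaris strains 151 genes differed, 12 higher and 139 lower with ba70. Between bb859 and bh11, 0 differed (922 at an unadjusted p under 0.05 in edgeR). The qs18 library with bb859 lay at -101.5 on the first principal component of the host samples (40.3% of variance), and the others at -48.6 to 33.2.

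Fold changes against the same uninfected samples correlated across genes by 0.72 between the classes of symbiont, and genes are not independent replicates. In 100 simulations with no effect and the same sharing of uninfected samples, the correlation was 0.66 (0.61 to 0.69). The covariance was 0.214 against a simulated 0.0949, a difference of 0.119. Of the genes called, 2 rose in both, where independent lists, a value that leaves out the shared controls, would share 0.0133. The simulated values already hold the sharing of controls, so under the simulated spread the covariance difference lies beyond it. The controls were too few to split, so the excess was not tested with separate controls. Both classes also differed from the uninfected samples in extraction and sampling point. These cannot be told apart here from a response shared between the classes.

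It was tested as a hypothesis whether bacterial genes with neighbouring identifiers change together. The correlation of log2 fold changes between consecutive identifiers was 0.55 in bh11, 0.61 in bb859, 0.74 in ba159 and 0.71 in ba70, above all 1000 shuffles of each strain (-0.05 to 0.06). The longest runs of identifiers that rose were 26, 32, 83 and 62, against at most 6, 6, 10 and 9 in 100 shuffles, and the longest that fell were 8, 8, 22 and 22, against 4, 6, 7 and 16. Genes that lie together may be regulated together, but no positions were available to test this.

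Other splits of the samples into groups of the same sizes were tested for each comparison with at least 3 samples per group. In each symbiont strain, and for the classes in libraries whose labels agree, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 1067, 1437, 3687, 4548 and 1, and the highest other count was 0 in each. By library name, 2 of 84 splits gave as many for P. agricolaris against uninfected (96 genes, highest other 145 with the 3 ba159 samples set apart), but so did 2 of the 27 that keep the samples per host strain, so chance was not excluded. For P. hayleyella or P. bonniea, 4 of 84 splits did (2 genes, highest other 820 with qs18 uninfected, qs18 with bh11 and qs9 uninfected set apart), and 3 of 27 within strains (highest other 4), so chance was not excluded. Between the classes, 2 of 100 splits drawn did (104 genes, highest other 208), and within strains 1 of 100, the real one (highest other 35). A regrouping of single samples within strains therefore rarely gave as many. Each class pooled 2 symbiont strains, and the labels do not say whether libraries came from separate cultures. The splits therefore cannot exclude chance for the classes as such. For infection, 4 of 100 splits drawn within strains gave as many, but 5 of 100 drawn without regard to strain did too, so chance was not excluded (1 gene, highest other 242 in both with the 3 ba159 samples set apart). The splits with 820 and 242 genes point to a structure of the samples other than the groups compared. In the comparisons with uninfected hosts, the highest other splits within strains were the 3 ba159 samples (145 and 242 genes) or 3 bb859 samples (4). These are exposure groups and not groups without effect, so such splits cannot decide whether chance gave the counts. For host strain, 1 of 100 splits drawn gave as many (1639 genes, highest other 1), so a regrouping of single samples did not give this count. The splits cannot tell strain from batch.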
